A study of Caenorhabditis elegans with 2 samples.

How the data were processed

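ChIP-seq of DVE-1 with a C-terminal GFP-FLAG tag was analysed from peak lists of 2 biological replicates of late embryonic C. elegans, per the labels, which also name the anti-GFP antibody, the whole-organism samples and sonication. Per the text descriptions deposited with the lists, the authors made 4 lists in each of the genome builds ce10 and ce11. These were 1 list per replicate, 1 list called on the reads of both replicates together, and 1 list thresholded by IDR, and the same control alignment served both replicates. The replicate and pooled lists hold peaks and background meant as input to IDR, and the pooled list has 30000 lines. The aligner, the peak caller, the treatment of reads that map to several places and the IDR settings are not given in the sources used here.

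The deposited lists give each peak a signal, the authors' own enrichment value from the peak caller, and this signal was used only to rank or filter peaks, and to compare them, within a list. The correlation of signals between replicates is the exception and describes peaks present in both. A further column for q-values fell slightly below 0 in the pooled lists and is treated as a score of the authors, per the labels of the peak format, and it was not used. The summit is the position that the authors give for each peak. All 1447 thresholded ce11 peaks were identical to the 1447 strongest peaks of the pooled list, and 1406 of them were 364 bp wide. Their signals ran from 78.9 to 917 with a median of 110. Depth per sample is unknown, because peak lists give no read totals. All intervals are exact Clopper-Pearson or conditional exact 95% intervals over peaks or genes, and they cover counting error only.

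Peak lists were compared with Ensembl release 115 gene models on the matching ce11 sequence, and ce10 coordinates were never combined with them. A replicate peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Chance overlap was estimated by shifting replicate 1 peaks along their chromosomes 100 times. Peaks per chromosome were compared with chromosome length by exact binomial tests, and the central 33.3% of the autosomes likewise. Each summit was assigned to the first class that held it, in the order promoter window, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. The promoter window reached from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. A gene was called a target when a thresholded summit lay in its window, over 19970 protein-coding nuclear genes.

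The 24 gene lists, 11 motifs, 7 gene types and the tests named in this paragraph were fixed before the data were examined, and 8 gene symbols in the lists matched no annotated gene. Lists and gene types were tested with Fisher's exact test, and motifs with McNemar's exact test on windows of 201 bp at the summit and 600 bp to 1 side of it, drawn at random. Signals were compared by 100000 permutations of the difference in medians. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The named genes were chosen by a rule fixed at the same time. It takes genes with 1 of the 25 strongest thresholded summits in their window, up to 4 members with the highest signal for each list past the threshold, and every target among the mitochondrial unfolded protein response regulators and the mitochondrial chaperones, proteases and import genes. It always takes dve-1, unc-119, hsp-6, hsp-60, ubl-5 and atfs-1. Telomere-like repeats and the 200 bp distance to tRNA and snoRNA genes were defined after the peaks were seen.

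Alternatives covered narrower and wider promoter windows, the peaks above the median signal, each replicate's own strongest peaks, assignment to the nearest gene within 2000 bp, genes with a pooled peak as background, exclusion of peaks within 20 kb of dve-1 and unc-119, stricter overlap, ce10 lists, gene share in place of length, and other motif windows and controls. Added after the data were examined were peaks found in both replicates, exclusion of telomere-like peaks, exclusion of peaks near tRNA or snoRNA genes, and shuffled motif controls. Tests of explanations for single patterns were also chosen later, as stated where they are given. Those on overlap of telomere-like peaks in both replicates, on the length of the stretch without peaks around dve-1 and on coverage of the mitochondrial genome were dropped, because the choice of peaks or the pattern itself fixed their outcome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 1. Overlaps were computed by own code, and the count of replicate 1 peaks overlapped in replicate 2 equalled the 6736 that bedtools 2.31.1 gave. The list test was tested on simulated data over 19970 genes. Members of 3 lists were 6 times as likely to be drawn for the summits placed at promoters. The remaining summits fell anywhere, so the members' excess among targets was below 6-fold. In 50 simulations the list test called cytosolic ribosomal proteins in 86% and chromatin regulators in 90%, but the respiratory chain in only 62%. Lists left unchanged were called in 8 of 950 tests (0.842%).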

Results

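Binding of DVE-1 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in late embryos of the nematode Caenorhabditis elegans. DVE-1 is a homeodomain protein known for its part in the mitochondrial unfolded protein response, the induction of chaperones and proteases when proteins misfold in mitochondria. The hermaphrodite worms carried an integrated transgene for DVE-1 with GFP and FLAG tags at its C terminus, in an unc-119 mutant background. Chromatin of whole animals was sheared by sonication and precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, so the comparisons were between the replicates, between bound sites and the rest of the genome, and between groups of genes. Other factors, stages and untagged worms were not analysed here. Peak lists give no read totals, so the depth of each library is unknown. Positions are on the ce11 build, and every peak signal is the authors' own value.

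The first question was where DVE-1-GFP peaks recurred between the replicates. The list filtered by the authors for reproducibility (IDR, the irreproducible discovery rate) held 1447 peaks, 1440 of them on the 6 nuclear chromosomes. Replicate 1 overlapped 1438 of them (99.4%, Clopper-Pearson 95% interval 98.8% to 99.7%), and replicate 2 also overlapped 1438. Both replicates overlapped 1429 of the peaks (98.8%, interval 98.04% to 99.26%). These shares were largely set in advance, since the thresholded peaks are the strongest called on the reads of both replicates together. The 7 mitochondrial thresholded peaks had no counterpart in replicate 2, which held 0 mitochondrial peaks. The replicates' own lists were longer, with 11568 and 15750 peaks, and shared less. Of the replicate 1 peaks, 6736 (58.2%, interval 57.3% to 59.1%) were overlapped in replicate 2, against a median of 11.0% and a maximum of 11.9% after 100 random shifts along the chromosomes. The shifts do not keep the position of peaks relative to promoters or repeats, and the same control alignment served both replicates. The excess over the shifts therefore need not reflect DVE-1 binding alone. The share followed peak rank, from 100% of the 500 strongest nuclear peaks of replicate 1 to 35.97% of ranks 8001 to 11547. When each replicate was limited to its 1447 strongest peaks, 966 thresholded peaks (66.8%, interval 64.3% to 69.2%) were overlapped in both. Over the 1429 peaks found in both, Spearman's rho of the signals was 0.514, and Pearson's r of their log2 values was 0.64. These correlations run across peaks within 1 pair of libraries, and peaks are not independent replicates.

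**Figure D1:**
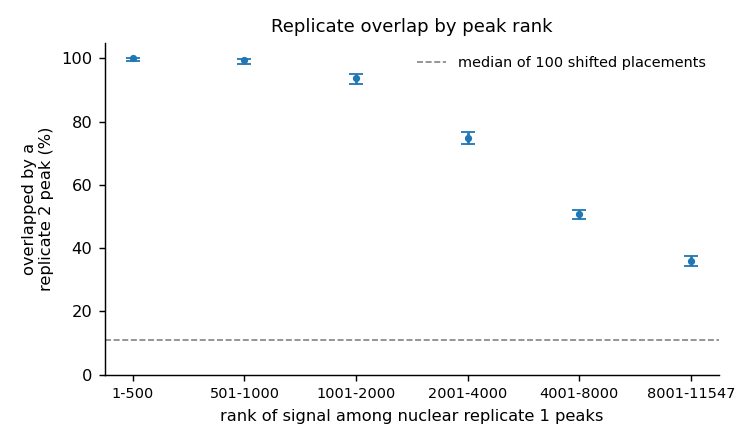
Share of nuclear replicate 1 peaks overlapped by a replicate 2 peak (y axis, percent) by rank of the authors' signal in replicate 1 (x axis). Points are shares with Clopper-Pearson 95% intervals, and the dashed line at 11.0% is the median of 100 shifted placements. The share falls from 100% in the 500 strongest peaks to 35.97% in ranks 8001 to 11547.

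Chromosomes I, II and III held more DVE-1-GFP peaks than their length would give, and chromosomes IV and V held fewer. Chromosome III had 19.1 peaks per Mb, 1.33 times its share by length (exact binomial test, two-sided, adjusted p = 4.92e-06 over 6 chromosomes), and chromosome V had 10.3 per Mb, 0.716 times (adjusted exact p = 6.33e-08). The ratios were 1.21 on I (adjusted exact p = 0.00123), 1.24 on II (0.000260) and 0.788 on IV (0.000260). The X chromosome had 229 peaks where 254 were expected, a ratio of 0.8999 that did not pass the test (adjusted exact p = 0.0840). On the autosomes, the central 33.3% of each chromosome held 381 of 1211 peaks (31.5%), which did not differ past the threshold from its share by length (adjusted exact p = 0.483). Both of these last ratios changed direction, that on X without passing in either case, when peaks on telomere-like repeats, described below, were left out. Those peaks were rare on X and absent from the central parts, so leaving them out could only raise both ratios. The X ratio was then 1.0996 (adjusted exact p = 0.123), and the central parts held 381 of 933 autosomal peaks (40.8%, adjusted exact p = 1.31e-05 against length). Against the share of protein-coding genes, the central parts were low with all peaks (ratio 0.826, adjusted exact p = 1.11e-05) and did not pass without telomere-like peaks (1.07, adjusted exact p = 0.161). Measured against the share of protein-coding genes, X was at 1.16 (adjusted exact p = 0.0188), and the excess on II missed the threshold at 1.098 (adjusted exact p = 0.0941). Clustered peaks are not independent, which these binomial tests do not allow for.

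Summits of DVE-1-GFP peaks lay mostly outside coding sequence and often just upstream of genes. A promoter window of a protein-coding gene, from 1000 bp upstream to 200 bp downstream of its annotated 5′ end, held 639 of 1440 nuclear summits (44.4%, interval 41.8% to 46.99%). These windows cover 21.5% of the nuclear genome, so the share was 2.07-fold higher (exact binomial test, two-sided, p = 1.06e-83). The fold depended on the window, at 3.14 with 500 bp upstream to 100 bp downstream (35.3% against 11.2%) and 1.46 with 2000 bp upstream to 500 bp downstream (58.1% against 39.9%). Outside the windows, coding exons held 1.25% of summits against 19.8% of the genome, and 3′ UTRs held 0.278% against 2.37%. Introns held 22.3% of summits against 29.95% of the genome, and intergenic sequence held 19.9% against 22.8%. Exons of non-coding genes held 11.0% of summits and cover 2.84% of the genome. Median signal was 107.7 at promoter summits and 111.8 at the other 801 summits, a difference that did not pass a permutation test (two-sided, p = 0.138). Many C. elegans genes are trans-spliced or sit in operons, so an annotated 5′ end need not be a transcription start.

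**Figure D2:**
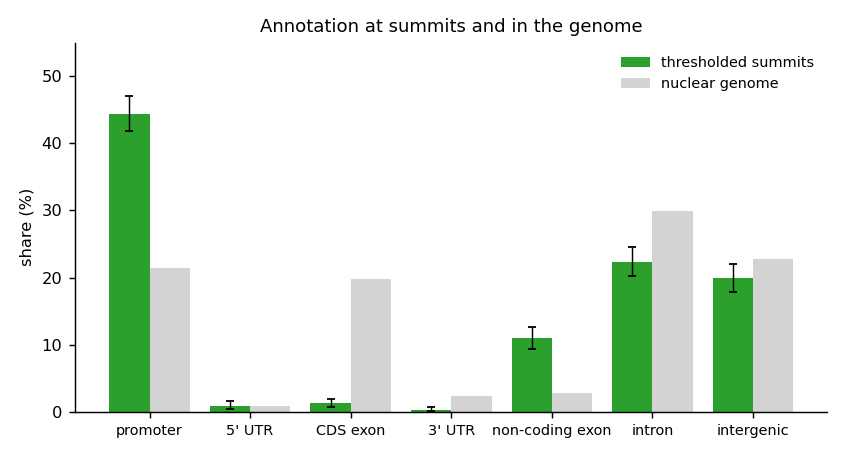
Share of the 1440 nuclear thresholded summits (green, with Clopper-Pearson 95% intervals) and of the nuclear genome (grey) in each annotation class, in percent. Each position is assigned to the first class from the left that holds it. Promoter windows hold 44.4% of summits and 21.5% of the genome, and coding exons hold 1.25% and 19.8%.

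The promoter windows of 865 of 19970 protein-coding genes (4.33%) held a thresholded summit, and these target genes were rich in components of protein synthesis, protein folding and respiration. Cytosolic ribosomal protein genes were the most frequent of the 24 gene lists, with 43 of 81 genes bound. Genes for chaperones and heat shock of the cytosol and endoplasmic reticulum, with stress regulators among them (17 of 47), and for the respiratory chain and ATP synthase (14 of 51) followed. Chemoreceptor genes were the least frequent of the lists past the threshold, with 9 of 1371 bound. In all, 10 lists were over-represented and 2 under-represented (Fisher's exact test, two-sided, adjusted p below 0.05 over the lists). Untagged worms and other factors were not compared, so these values do not show whether the genes, or the small RNA genes below, are particular to DVE-1.

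Ribosomal protein genes had an odds ratio of 26.2 (95% interval 16.46 to 41.96, adjusted exact p = 7.91e-36) over 41 distinct summits. It was lower, at 7.77 (22 of 81 bound), with only the nearest gene assigned and 11.7 against genes with a pooled peak. The strongest stood 269 bp upstream of rpl-3 (chromosome III, 3867854 to 3869587), with signal 444, rank 9 of the list. Next came rpl-15 (signal 346, 345 bp upstream), rpl-35 (300.9, 449 bp upstream) and rps-12 (253, 170 bp upstream). Genes for mitochondrial ribosomal proteins, which are made in the cytosol and imported, were bound at 8 of 70 (odds ratio 2.87, interval 1.18 to 6.03, adjusted exact p = 0.0211). Their highest signals were at mrpl-23 (205, at a summit within 200 bp of a snoRNA gene), mrps-7 (157), mrpl-15 (138) and mrpl-49 (123, at the summit shared with rpl-28). The call was lost with the narrow window of 500 bp upstream to 100 bp downstream (adjusted exact p = 0.151), with the nearest gene (0.0845) and against genes with a pooled peak (0.231).

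The list of cytosolic and endoplasmic reticulum chaperone and heat shock genes had an odds ratio of 12.7 (interval 6.56 to 24.0, adjusted exact p = 3.67e-11), which fell to 5.56 (10 of 47 bound) with the nearest gene and 8.73 against genes with a pooled peak. The highest signals were at hsp-1, a constitutive HSP70 chaperone (216, 392 bp upstream), and xbp-1, a transcription factor of the endoplasmic reticulum stress response (185, 13 bp upstream). The protein disulfide isomerase gene pdi-3 (145) and the chaperone gene hsp-110 (141) came next. Among the 17 bound genes, xbp-1, ire-1 and atf-6 encode regulators of the endoplasmic reticulum stress response and no chaperone. Respiratory chain and ATP synthase genes had an odds ratio of 8.48 (interval 4.22 to 16.12, adjusted exact p = 1.28e-07), with 5.67 for the nearest gene and 4.68 against genes with a pooled peak. They were led by the cytochrome c oxidase subunits cox-5B (185) and cox-5A (149), the oxidase assembly factor sco-1 (148) and atp-2 (143), the beta subunit of ATP synthase.

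Regulators of the mitochondrial unfolded protein response were bound at 6 of 24 genes, against 4.31% of the other genes (odds ratio 7.40, interval 2.40 to 19.5, adjusted exact p = 0.00153). These were cbp-1, a histone acetyltransferase (chromosome III, 9766509 to 9774825, signal 202, 920 bp upstream), the bZIP factor gene cebp-1 (X, 1452695 to 1453868, signal 168, 698 bp upstream) and jmjd-1.2, a histone demethylase (IV, 4660991 to 4665212, signal 100.6, 378 bp upstream). The others were rheb-1, a GTPase of the TOR pathway (III, 9454163 to 9456030, signal 94.97), atfs-1, the bZIP factor that leads the response (V, 14193663 to 14197700, signal 82.3), and atf-4 (X, 14809156 to 14810810, signal 82.3). The lists overlap, as cbp-1 and jmjd-1.2 are also counted among chromatin regulators and rheb-1 among autophagy and lysosome genes. The atfs-1 summit was 59 bp upstream of the gene, at rank 1334 of 1447. This list's call was lost among the peaks above the median signal, where the odds ratio was 4.29 (adjusted exact p = 0.236), and it was 3.98 against genes with a pooled peak (adjusted exact p = 0.0359).

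Genes for mitochondrial chaperones, proteases and import were bound at 5 of 30 (odds ratio 4.44, interval 1.32 to 11.8, adjusted exact p = 0.0190). A single summit with signal 169, at rank 246, lay 605 bp upstream of hsp-60, the mitochondrial chaperonin gene (III, 1619742 to 1625803), and 208 bp upstream of the divergent gene Y22D7AL.10, a chaperonin partner of hsp-60. The other members were ddp-1 (139) and tomm-20 (134), both of protein import, and phb-2 (130), a prohibitin. The call was lost with windows of 2000 bp upstream to 500 bp downstream (adjusted exact p = 0.0653), with only the nearest gene assigned (0.0845) and against genes with a peak in the pooled list (0.144). The mitochondrial HSP70 gene hsp-6 (V, 4824124 to 4826760) and the ubiquitin-like gene ubl-5 (I, 5607826 to 5608841), both classic members of the response, had no thresholded summit. In the pooled list, before thresholding, each had 1 summit, with signal 59.2 at rank 2572 for hsp-6 and 74.5 at rank 1606 for ubl-5.

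Chromatin regulators, histones, autophagy and lysosome genes and cell cycle genes made up the remaining over-represented lists. Chromatin regulators were bound at 16 of 98 genes (odds ratio 4.37, interval 2.38 to 7.57, adjusted exact p = 2.18e-05, and 2.87 with the nearest gene or 2.78 against genes with a pooled peak), led by the methyltransferase gene set-16 (216), cbp-1 (202), lin-54 (169), a DNA-binding subunit of the DREAM complex, and hat-1 (128). The lin-54 summit was shared with the ribosomal protein gene rpl-12 and lay nearer to rpl-12 (41 bp upstream, against 352 bp for lin-54). Likewise, the member set-21 shared its summit with rpl-7A (53 bp upstream, against 201 bp for set-21). Histone genes were bound at 14 of 80 (odds ratio 4.74, interval 2.45 to 8.58, adjusted exact p = 3.10e-05) through 9 distinct summits, since neighbouring histone genes share an upstream region. The highest were his-67 and his-68 (261, 1 shared summit), his-37 (250) and his-61 (203). Histone genes have near-identical copies, so a peak at any one of them is uncertain. Autophagy and lysosome genes were bound at 9 of 58 (odds ratio 4.09, interval 1.76 to 8.45, adjusted exact p = 0.00244), with the proton pump genes vha-8 (145), vha-12 (136), vha-1 (118) and vha-15 (107) at the top. Cell cycle genes were bound at 8 of 53 (odds ratio 3.95, interval 1.60 to 8.51, adjusted exact p = 0.00503), led by cdk-7 (129), lin-23 (124), cdk-5 (118) and the replication gene cdc-6 (99.3). Calls were lost for autophagy and lysosome genes above the median signal (adjusted exact p = 0.262), with the nearest gene (0.0845) and against genes with a pooled peak (0.129). They were lost for cell cycle genes above the median signal (adjusted exact p = 0.236) and against genes with a pooled peak (0.139), and for histones with the nearest gene (0.0720).

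Chemoreceptor genes had an odds ratio of 0.137 (interval 0.0623 to 0.262, adjusted exact p = 7.18e-16). The depletion was weaker with the nearest gene (0.228) and against genes with a pooled peak (0.352, 9 of 224 bound, adjusted exact p = 0.00264). It was stronger with the narrow window of 500 bp upstream to 100 bp downstream (0.0803, 4 of 1371 bound). Their strongest summits were upstream of sre-23 (335, within 200 bp of a snoRNA gene), srg-34 (211, on a telomere-like repeat), srh-269 (123, within 200 bp of a tRNA gene) and sri-5 (118.7). The list was taken by gene name, and 1 of its 9 targets, srrt-1, encodes an RNA-processing factor and no receptor. C-type lectins, lysozymes and other defence genes were bound at 5 of 341 (odds ratio 0.325, interval 0.104 to 0.769, adjusted exact p = 0.0111), which were clec-126 (187, within 200 bp of a tRNA gene), cnc-10 (156), fipr-17 (114), clec-178 (81.8) and clec-86 (79.9). Their odds ratio was 0.202 without replicate 1 and 0.393 without replicate 2. The defence call was lost above the median signal (adjusted exact p = 0.349), with the nearest gene (0.132) and against genes with a pooled peak (0.129).

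Tissue genes and developmental transcription factors did not pass the test in either direction. Among homeobox genes 1 of 101 was bound (ceh-38, adjusted exact p = 0.231), and among forkhead, T-box and GATA factors 0 of 48 (adjusted exact p = 0.409), which allows an odds ratio of up to 1.76. Nuclear hormone receptor genes were bound at 15 of 274 (adjusted exact p = 0.440), and basic helix-loop-helix genes at 2 of 41 (mdl-1 and hlh-11, adjusted exact p = 0.728). Neuronal genes were bound at 4 of 63 (unc-76, unc-40, snb-1 and syd-2, adjusted exact p = 0.440), muscle genes at 2 of 57 (unc-60 and unc-23, adjusted exact p = 1) and intestinal genes at 1 of 58 (act-5, adjusted exact p = 0.567). Epidermal genes were bound at 3 of 50 (spc-1, hmp-1 and pkc-3, adjusted exact p = 0.546), germline genes at 2 of 100 (cgh-1 and mex-1, adjusted exact p = 0.439) and collagen genes at 4 of 185 (col-42, col-38, col-185 and col-107, adjusted exact p = 0.320). Detoxification enzymes were bound at 3 of 187 (gst-27, gst-5 and gst-13, adjusted exact p = 0.128), and neuropeptide and insulin genes at 3 of 140 (ins-39, flp-23 and nlp-29, adjusted exact p = 0.414). Homeobox genes did pass as under-represented with the wide window (odds ratio 0.151, adjusted exact p = 0.0426), and detoxification enzymes did without replicate 1 (0.247, adjusted exact p = 0.0483). The members named for these lists were chosen after their values were seen. The col-42 summit was on a telomere-like repeat, and the col-38 summit was shared with rpl-5. Those of col-185 and flp-23 were within 200 bp of a tRNA gene, and that of gst-27 was within 200 bp of a snoRNA gene. Of the 12 lists past the threshold, 5 kept their call in each of 11 alternatives, namely cytosolic ribosomal proteins, cytosolic and endoplasmic reticulum chaperone and heat shock genes, the respiratory chain, chromatin regulators and chemoreceptors. Neighbouring genes share summits, 216 of the 639 promoter summits (33.8%) lying in windows of several genes, so the genes are not fully independent in these tests.

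**Figure D3:**
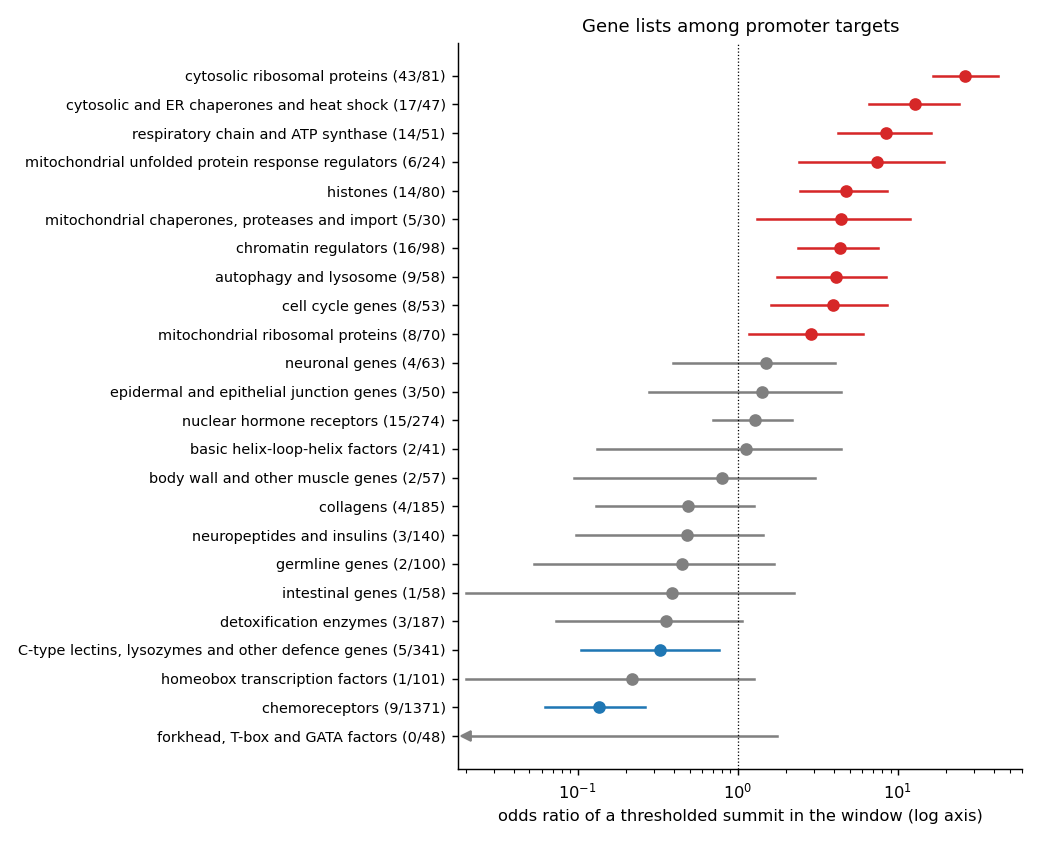
Odds ratio of having a thresholded summit in the promoter window (x axis, log scale) for each of the 24 gene lists, with 95% intervals as lines. Red lists are over-represented and blue lists under-represented at adjusted p below 0.05, grey lists did not pass, and bound and total genes are in parentheses. Bars are clipped at the left edge, where a triangle marks a list with 0 bound genes. Cytosolic ribosomal proteins lie highest at 26.2 and chemoreceptors are lowest of the lists past the threshold at 0.137.

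Genes for small RNAs, too, carried DVE-1-GFP peaks. A summit lay in the window of 185 of 612 tRNA genes (30.2%) and 83 of 346 snoRNA genes (24.0%), against 4.33% of protein-coding genes. The odds ratios were 9.57 for tRNA genes (interval 7.90 to 11.6, adjusted exact p = 9.55e-93) and 6.97 for snoRNA genes (interval 5.33 to 9.04, adjusted exact p = 1.17e-35, Fisher's exact test over 7 gene types). They were 9.04 and 5.33 for genes more than 1 kb from a protein-coding 5′ end (adjusted exact p = 1.43e-61 and 2.50e-15). snRNA genes were at 10.1% (odds ratio 2.48, adjusted exact p = 0.00596), a call lost more than 1 kb from protein-coding genes (odds ratio 1.16, adjusted exact p = 0.909). miRNA genes (6.13%, adjusted exact p = 0.194) and rRNA genes (0 of 20, adjusted exact p = 1) did not pass, though miRNA genes did with the wide window (odds ratio 1.75, adjusted exact p = 0.0133) and above the median signal (2.27, adjusted exact p = 0.0159). Pseudogenes (0.471%, odds ratio 0.104, adjusted exact p = 6.92e-26) and other non-coding RNA genes (2.55%, odds ratio 0.578, adjusted exact p = 2.70e-24) were bound less often. The class of other non-coding RNA genes pooled 23408 genes and was not split by kind, so its share need not hold for each kind. tRNA genes occur in clusters and near-identical copies, so they too are not independent and a peak at a single copy is uncertain.

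The 25 strongest thresholded peaks lay at a mixture of promoters, small RNA genes and repeats. The strongest of all, with signal 917, was intergenic on chromosome IV (1785204 to 1785534), and its summit window of 201 bp held 6 copies of TTAGGC, the unit of C. elegans telomeres. The next, with signal 846 (IV, 2403404 to 2403727), had 11 copies in an exon of a non-coding gene. Promoter summits among the 25 belonged to rpl-3, rpl-15, cdc-48.1, which encodes the AAA ATPase p97 (signal 406, 169 bp upstream, II, 10563452 to 10563657), and iff-2, a translation factor eIF5A gene (337, 66 bp upstream, II, 8561376 to 8561525). The rpl-15 and iff-2 summits were also in the windows of K11H12.8 and F54C9.14. The others were upstream of Y41D4B.6 (427, with 13 TTAGGC copies), of Y87G2A.1 and Y87G2A.18 (386), of R13A5.11 (375) and of H41C03.3 (348, next to the splice leader RNA gene sls-2.1). The peak at rank 7 (signal 559) was on the mitochondrial genome.

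Telomere-like repeats, taken as at least 3 TTAGGC copies within 100 bp of the summit, were a class defined only after these peaks were seen. They held 282 of 1440 nuclear thresholded summits (19.6%, interval 17.6% to 21.7%), and windows 600 bp away met the same definition in 0.694% of cases. Among the 24 nuclear peaks of ranks 1 to 25 the share was 45.8% (interval 25.6% to 67.2%), and in ranks 1001 to 1447 it was 13.0% (interval 10.002% to 16.45%). Introns held 143 of the 282 summits (50.7%), intergenic sequence 69 and promoter windows 39. All 278 on autosomes lay outside the central part of their chromosome, with 0 of 278 inside it against 381 of 933 other peaks (Fisher's exact test, p = 5.85e-54). Only 4 were on X, in introns at 1495984 to 1496347 and 14721662 to 14722025, and between genes at 1834413 to 1834776 and 17509584 to 17509947. The share of all such repeats that lie centrally was not counted, so the lack of central peaks may reflect the position of the repeats alone.

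**Figure D4:**
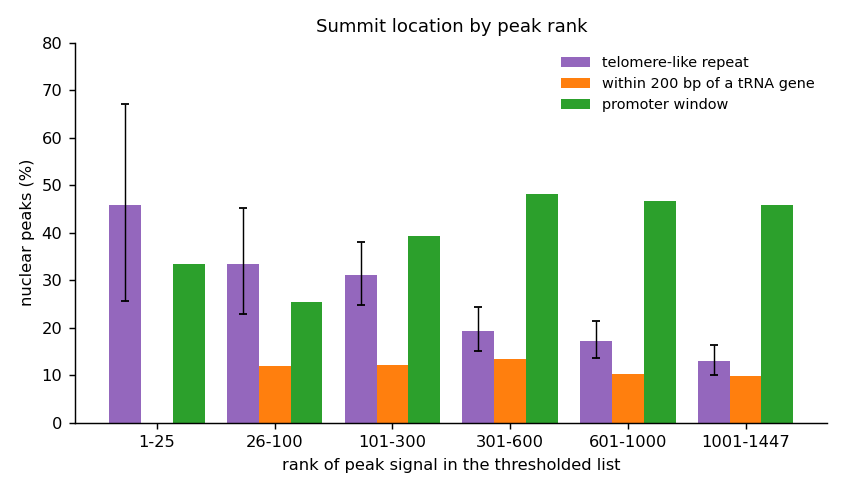
Share of nuclear thresholded peaks (y axis, percent) with a summit on a telomere-like repeat (purple, with Clopper-Pearson 95% intervals), within 200 bp of a tRNA gene (orange) or in a promoter window (green), by rank of signal (x axis). A peak can be in more than 1 class. The telomere-like share is 45.8% in ranks 1 to 25 and 13.0% in ranks 1001 to 1447, and the tRNA share is 0 in ranks 1 to 25 and between 9.84% and 13.4% in the other bins.

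Sequence at the summits was rich in GAGAGA and in GC, and poor in the homeodomain core TAATTA. GAGAGA occurred within 100 bp of 34.9% of summits and in 11.7% of paired windows 600 bp away (exact McNemar test, adjusted exact p = 2.72e-48 over 11 motifs). CCGCCC followed, at 9.93% against 3.19% (adjusted exact p = 2.41e-13). Against summit windows shuffled with their dinucleotides kept, both were weaker, with controls at 17.5% for GAGAGA (adjusted exact p = 2.59e-36) and 6.11% for CCGCCC (adjusted exact p = 0.000590). TAATTA was at 2.78% against 8.89% (adjusted exact p = 4.19e-12), and it stayed below its control, at 5.21%, when each summit window was shuffled in this way (adjusted exact p = 0.00254). TGATAA (8.19% against 18.3%), the heat shock element GAANNTTC (7.71% against 16.39%) and TTTTTTTT (9.03% against 20.8%) were lower than in the windows 600 bp away (adjusted exact p = 1.89e-14, 1.87e-12 and 3.49e-19) but not lower than in the shuffled windows. Without replicate 2, TGATAA was at 12.4% against 16.42% (adjusted exact p = 0.00404). ATCGAT (8.13% against 7.57%), CACGTG (4.65% against 3.61%), TGACGTCA (0.903% against 1.25%), TGATGCAA (0.694% against 0.625%) and TGTTTAC (2.57% against 2.78%) did not pass. Against the shuffled windows ATCGAT (1.8 times, adjusted exact p = 0.000264) and CACGTG (1.675 times, adjusted exact p = 0.0238) did pass. GC content was 45.5% ± 6.07 (SD) at summits and 36.9% ± 7.72 in the paired windows. An exploratory scan covered 2080 6-mers. Among those more frequent at summits, the highest ranks went to CCTAAG (20.5% against 2.92%) and GGCTTA (22.4% against 4.65%). Both are sequences of the telomere-like repeats, and AGAGAC (28.1% against 7.22%) came next. AAAATT, which was less frequent at summits, ranked between CCTAAG and GGCTTA by adjusted p. After telomere-like peaks were left out, GAGAGA (42.9% against 11.1%) and ACGCAG (27.6% against 3.45%) led the 6-mers more frequent at summits. The full scan called 547 6-mers more frequent at summits than in the windows 600 bp away, and 631 less frequent. With shuffled summit windows as control, the counts were 246 and 611. AAAATT was then more frequent at summits (31.04% against 24.65%, adjusted exact p = 2.98e-05). CCTAAG was at 20.5% against 16.04%, and AGAGAC at 28.1% against 11.8%. A difference from the windows 600 bp away alone therefore does not separate a 6-mer from base composition.

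The locus of the tagged gene was free of peaks. No peak of any of the 4 ce11 lists lay within 5 kb of dve-1 (X, 427035 to 433812, minus strand). Around unc-119 (III, 10902641 to 10908935), the gene mutated in the strain, no thresholded peak was found within 5 kb. The pooled list had 5 peaks there, the strongest with signal 32.98 at rank 9121 of 30000, and each replicate list had 2. Reads from transgene copies of dve-1 or of the unc-119 rescue in the strain map to these native loci, so peaks there can reflect copy number.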

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

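All tests in this part were chosen only after the result was seen. Peaks on the mitochondrial genome stood out because they lie outside the nuclear comparisons, and because the replicates differed in them. Replicate 1 had 21 mitochondrial peaks and replicate 2 had 0. The pooled list had 12, and the thresholded list had 7, the strongest with signal 559 at rank 7. The difference between the replicates was not tested.

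Replicate 2 had 15750 nuclear peaks, more than the 11547 of replicate 1, so its list was not shorter as a whole. These counts were known before the comparison was chosen, and the lists include background. They therefore do not decide whether mitochondrial peaks could be called in replicate 2. Replicate 1 peaks covered 49.1% of the 13794 bp of the mitochondrial genome and 4.05% of the nuclear genome, which restates the number of peaks and favours no explanation. Even coverage of an abundant genome and mitochondrial carry-over stay open, as the reads were not analysed here. No biological explanation was tested, since both replicates belong to 1 group.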

How the results depend on the processing

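Most alternatives left the results where they were, and among those that moved, the main results, the reversals, the changed calls and some changes in size are given here; the cause was not tested. No paired analysis was possible because there was only 1 group. Thresholded peaks overlapped in both replicates fell to 95.6% with 50% of both peaks required and to 94.2% with summits within 100 bp. Overlap in replicate 1 moved to 96.96% and 95.99% (and 99.7% above the median signal), in replicate 2 to 98.5% and 98.1%, of replicate 1 peaks in replicate 2 to 51.9% and 43.8%, and the other way to 38.4% and 32.2%. With gene share, the ratio on II weakened to 1.098. The ratio on X reversed to 1.16 with gene share in place of length and to 1.0996 without telomere-like peaks, and it was 0.906 to 0.907 when a replicate was left out. The central parts of autosomes reversed to 1.23 without telomere-like peaks, moved further to 0.826 with gene share, and ran from 0.926 to 1.02 when a replicate was left out. Over-represented gene lists fell from 10 to 6 with the nearest gene, and likewise to 6 with genes holding a pooled summit as background. Under-represented lists fell from 2 to 1 in both, and to 1 among peaks above the median signal. Calls lost, with odds ratios, were mitochondrial ribosomal proteins (2.267 narrow window, 2.277 nearest gene, 1.863 pooled background), mitochondrial chaperones (3.04 wide window, 3.15 nearest, 2.53 pooled), autophagy (2.575 above the median signal, 2.363 nearest, 2.098 pooled), cell cycle (2.83 above the median, 2.155 pooled), defence (0.413 above the median, 0.549 nearest, 0.426 pooled), histones (2.278 nearest), the stress response regulators (4.29 above the median) and snRNA genes (1.697 wide window, 1.16 over 1 kb from coding genes). Calls gained were homeobox (0.151 wide window), detoxification (0.247 without replicate 1) and miRNA genes (1.75 wide window, 2.27 above the median). Above the median, mitochondrial chaperones rose to 9.50 and mitochondrial ribosomal proteins to 4.46. Enriched motifs rose to 4 with shuffled controls, and promoter signal minus other signal reversed to 0.645 without telomere-like peaks, against -2.97 and -1.69 when a replicate was left out.

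Reversed odds ratios all belonged to lists that had not passed. Muscle genes reached 1.07 with the narrow window, 1.14 with the wide window and 1.13 with the nearest gene. Epidermal genes reached 0.598 with the narrow window, 0 above the median signal and from 0.452 to 0.961 when a replicate was left out, but 1.48 without telomere-like peaks. Nuclear hormone receptors reached 0.517 above the median signal and ran from 0.838 to 1.06 when a replicate was left out, and basic helix-loop-helix factors ran from 0.554 to 2.5001. With the nearest gene, forkhead, T-box and GATA factors reached 1.36 and neuropeptides 1.24.

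Among motifs, summit over control share of ATCGAT reached 0.804 within 50 bp and 0.909 above the median signal, and ran from 0.786 to 1.02 with a replicate left out, but reached 1.303 without telomere-like peaks, and with shuffled controls it passed at 1.8, as did CACGTG at 1.675. TGATGCAA reached 0.143 within 50 bp, 0.625 at peaks in both replicates and 0.833 with shuffled controls, with 0.90 to 1 on leaving out a replicate. TGTTTAC reached 1.32 with controls 1000 bp away, 1.12 at peaks in both replicates, 1.37 without telomere-like peaks and 1.68 with shuffled controls, with 1.12 to 1.41 on leaving out a replicate. TGACGTCA reached 1.5 without telomere-like peaks and 1.86 with shuffled controls, and ran from 0.52 to 0.625 with a replicate left out. Shuffled controls also reversed TGATAA to 1.009, GAANNTTC to 1.11 and TTTTTTTT to 1.11, which had passed against windows 600 bp away. Within 50 bp, TAATTA fell to 0.101 and TTTTTTTT to 0.146, and above the median signal TGATAA fell to 0.240.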

Other observations

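The comparisons of arrays of similar regularity, of the length of the dve-1 stretch and of overlap at telomere-like peaks were chosen only after the result was seen, as were the comparisons of X with the autosomes and of tRNA genes by chromosome. tRNA genes with a thresholded summit within 200 bp were found on every chromosome, from 16 of 78 (20.5%) on V to 26 of 64 (40.6%) on III, and X, with 276 tRNA genes, had 76 of them (27.5%). Of the 1440 nuclear thresholded peaks, 158 (11.0%) were within 200 bp of a tRNA gene and 62 (4.31%) within 200 bp of a snoRNA gene. Scanned over the genome, tandem arrays with 5 or more TTAGGC copies per 200 bp numbered 500 on the autosomes and 15 on X. A thresholded summit was on 240 of the autosomal arrays (48.0%) and 2 of those on X (13.3%, Fisher's exact test, odds ratio 0.167, interval 0.0181 to 0.750, p = 0.00805).

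Telomere-like repeats lay under 11 of the 24 nuclear peaks of ranks 1 to 25, and pile-up on tandem repeats of any sequence is argued against, since 242 of 515 telomere-like arrays (46.99%) held a thresholded summit and 5 of 492 other arrays with units of 5 to 10 bp did (1.02%), an odds ratio of 86.04 (interval 35.7 to 271, Fisher's exact test, p = 3.15e-78). TTAGGC was singled out because strong thresholded peaks lay on it, so the share of its arrays, the odds ratio and its p are not independent of that choice. The argument rests on the low share of the other arrays. By regularity, the telomere-like and other shares were 32.4% and 0.533% at a self-match of 0.6 to 0.7, 68.6% and 1.92% up to 0.8, 65% and 3.33% up to 0.9, and 20% (2 of 10 arrays) and 2.86% above 0.9. Overlap in both replicates was 99.6% for telomere-like peaks and 98.8% for the whole thresholded list. The thresholded peaks are the strongest called on the reads of both replicates together, so this overlap was largely set in advance and argues for and against nothing. Recognition of the repeat by the tagged protein is a hypothesis that predicts more summits with more copies, and Spearman's rho was 0.229 across arrays (permutation test, p = 0.0001, the smallest that 10000 permutations can give) and 0.90 over the 5 bins of copies for which the test had been written, though arrays with more copies were also longer and few of the most regular held a summit. Extra reads from telomeres themselves, or another protein brought down with the antibody, may give the same pattern, and without untagged worms or reads these stay open.

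No peak of any list lay near dve-1. The pooled list had no summit from X 410359 to 451177, a stretch of 40.8 kb, and only 2.06% of the nuclear genome lies in stretches that long. The corresponding shares were 3.14% and 4.49% in the replicate lists and 71.8% in the thresholded list. These lengths restate the lack of peaks, so extra copies of the region in the transgene, which could raise the control coverage if the control came from the same strain, stay open and untested. The stretch held 4 protein-coding 5′ ends against a median of 8 in stretches of that length, with the lowest 5% at 3, so that count does not decide whether the region has few peaks because it has few genes.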
